A study of Mus musculus with 8 samples.

How the data were processed

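Liver RNA of hypophysectomized male mice, untreated or killed 30, 90 or 240 min after a single injection of GH, was sequenced in 8 libraries, 2 pools for each of 4 groups. The legend gives 4 mice per pool and the series design speaks of 8 individual RNA samples pooled into 2 replicates per condition. The labels' treatment protocol mentions a vehicle injection for controls, while the design text calls them untreated, and they are called untreated here. If the controls were not injected, effects of the injection itself cannot be told apart from those of GH in any of the comparisons. Libraries were made from poly-A RNA with a strand-specific kit, per the labels' protocols. TopHat2, featureCounts and edgeR and the mm9 build are named, with no versions or settings, per the submitters' processing notes.

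The FPKM values are the authors' means over the pools of a group, for reads over the gene body and, separately, for intronic reads, per the file headers and legend. The ratio is the authors' normalized expression ratio of treated over untreated, per the file headers. It differs from the quotient of the FPKM means by a nearly constant factor per comparison. The adjusted p-value is the authors', per the file headers, and how it was adjusted is not given in the sources used here. How many of the reads were filtered, and which length and total stand behind the intronic FPKM, are not given in the sources used here either.

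Before the data were examined, a count test across the 8 libraries was planned for every gene and list, with direct tests between times. The table holds means, ratios and adjusted p-values and no value per library, so no test was run here and the authors' comparisons are described, as the plan provided for that case. A gene was called where the authors' adjusted p was below 0.05. Pools of several mice measure the spread between pools, not between mice. The genes named in the text were fixed by a rule made before the data were examined: the 10 largest increases and 10 largest decreases among called genes with at least 1 FPKM in the higher group and a given name, 13 genes chosen beforehand, and up to 4 members per list with the smallest adjusted p, only called ones where a list had any. The parts of the rule on agreement of single pools and on differences between times could not be applied. Only some of the genes that the rule names are printed. Genes named outside this rule were chosen after their values were seen; these are the genes whose intronic values are given beside their gene body values and those in the closing observations.

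The 33 gene lists were fixed before the data were examined. For a list, members with a mean of at least 1 FPKM over the 4 groups, and for introns also at least 0.01 intronic FPKM, were counted as measured, and lists with fewer than 5 were not summarised. The median log2 ratio was placed among 10000 random lists with as many genes in each of 10 classes of expression. This describes these libraries and gives no p-value. Length and GC content of the longest GENCODE M21 transcript were matched by symbol to 96.1% of the 10736 measured genes and used as properties only, since that annotation is on another build than mm9. A trend with log2 length and GC, with squares and product, was fitted by robust regression per comparison and subtracted. The list step and the trend removal were tested on simulated data from 10314 genes, where 5 of 5 lists shifted by 0.5 and 5 of 5 shifted by 1 were outside the central 95%, as were 10 of 200 unchanged lists of short genes. The simulated noise was independent between genes, and the simulated trend was linear in log2 length and GC, a form that the fitted trend contains. Correlated genes and other shapes of the trend were not covered.

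Depth was recovered from the authors' mean FPKM of genes at a single location, where the most frequent smallest steps give the totals of the 2 libraries behind each mean. Among low values of such genes without intronic signal, 73.8% in the untreated group and 71.2%, 74.4% and 72.1% at 30, 90 and 240 min were whole reads within a relative tolerance of 0.0001, and no counts of single libraries were rebuilt. Shared controls were simulated with 100 sets of unchanged groups. Every gene drew normal noise of equal spread for each treated group and for 1 control shared by both. As many top genes were then taken as had been called, whatever their size. No value of the untreated pools entered, and the simulated correlation follows from the equal spread by construction. Alternatives tried were a stricter adjusted p of 0.01, a minimum change of 2-fold, a filter on low values against none, quotients of the FPKM means with pseudocounts of 1 and 0.1, and, chosen after seeing the data, the FPKM filter on calls, removal of the length and GC trend and random lists matched on length and GC as well. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.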

Results

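Liver RNA was profiled in hypophysectomized male CD-1 mice, an outbred strain. Removal of the pituitary takes away the source of growth hormone (GH), so that a later injection acts as a single pulse. Surgery was done at 7 weeks of age and livers were taken at 11 weeks. Animals were left untreated or received an intraperitoneal injection of recombinant rat GH at 125 ng per g body weight and were killed 30, 90 or 240 min later. Each of the 4 groups was represented by 2 pools of RNA, with 4 mice per pool according to the legend, and the 8 libraries were strand-specific and made from poly-A RNA. The deposited table gives the authors' mean FPKM per group, their ratio to the untreated pools and an adjusted p for 24197 genes. It does so for reads over the gene body and again for intronic reads, which come largely from unspliced RNA. It holds no value of a single pool, so no spread between pools can be given for any value, and a call below means that the authors' adjusted p was below 0.05.

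Library totals were recovered from the smallest FPKM values, which are steps of single reads. The untreated pools held 7440000 and 10520000 reads, and the pools at 30 min 9500000 and 9850000. Those at 90 min held 15380000 and 17120000, and those at 240 min 5940000 and 14150000. In the smallest library, 3 reads on a transcript of 1 kb correspond to a group mean of 0.253 FPKM, and this floor covers counting error only. Changes of genes near that level were not resolvable at this depth.

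**Figure D1:**
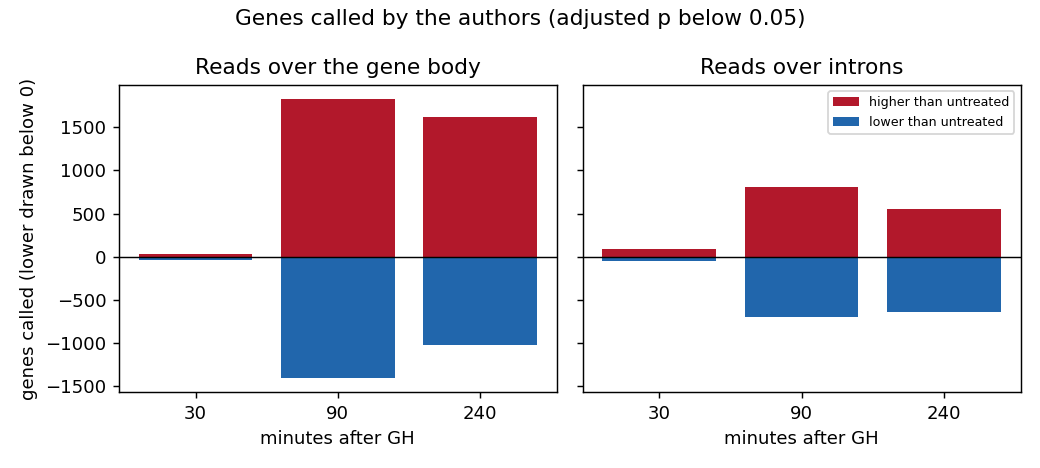
Number of genes called at each time after GH (x axis, min) in the authors' deposited table, for reads over the gene body (left) and over introns (right), with higher genes above 0 and lower genes below 0. Gene body calls numbered 64, 3240 and 2642 at 30, 90 and 240 min.

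The comparison of livers 30 min after GH with untreated livers addressed the earliest response to the pulse. Feedback inhibitors of GH signalling were among the genes that were higher. In the authors' deposited table, Socs2, a suppressor of cytokine signalling induced through STAT5, was 13.8-fold higher (from 1.18 to 15.2 FPKM, adjusted p = 4.5e-05), and Cish, which encodes a related inhibitor, was 7.1-fold higher (adjusted p = 0.00011). The proto-oncogene transcription factor Myc rose 7.89-fold (adjusted p = 1.5e-14) and Phlda1 5.79-fold, from 30.4 to 168 FPKM, in the authors' deposited table. Among the genes that fell, Igfbp1, which encodes an IGF-binding protein, was 3.78-fold lower, the orphan nuclear receptor Nr4a1 5.74-fold lower and the chemokine Cxcl10 5.09-fold lower in the authors' deposited table.

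In total 64 genes were called over the gene body in the authors' deposited table, 28 higher and 36 lower, and all of them differed by at least 2-fold. Among the largest increases in the authors' deposited table was the carboxylesterase gene Ces2b. Its untreated level of few reads (0.0709 FPKM) leaves the size unresolved. The carboxylesterase gene Ces3b (log2 ratio 2.97), Nrep (2.39), Ankrd37 (2.07) and the Wnt receptor Fzd7 (1.85) were also among them. So was Tchh (3.18), from a low level of 0.143 FPKM, in the authors' deposited table. The largest decreases in the authors' deposited table included the nicotinic acid receptor Hcar2 (log2 ratio -2.54), the stress-inducible Gadd45b (-2.45), the inflammasome sensor Nlrp3 (-2.45), the chemokines Ccl2 (-2.21) and Cxcl13 (-2.20), the transcription factor Cebpb (-2.04) and the NF-kB inhibitor Tnfaip3 (-2.02). Several genes fixed beforehand did not pass: the authors' deposited table lists Igf1, the growth factor that carries much of the action of GH, at 2.17-fold (adjusted p = 0.118), the liver transcription factor Onecut1 at 2.63-fold (adjusted p = 0.182) and Igfals, a partner of IGF in plasma, at 2.25-fold (adjusted p = 0.439). The log2 ratios of Socs3 (-0.01), Bcl6 (-0.71), Fos (-0.52), Egr1 (0.58), Junb (-0.81), Ghr (0.34) and Cux2 (-0.78) were not called in the authors' deposited table either.

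By gene list, the early targets of GH and STAT5 had 2 higher and 1 lower of 26 measured members called in the authors' deposited table, with a median log2 ratio of -0.06 at percentile 8.54 of the random lists matched on expression. With a trend with transcript length and GC content removed, this median was 0.01, at percentile 59.3. Without that step it lay at percentile 58.25 among random lists matched also on length and GC. The acute-phase and inflammatory genes had 4 members lower and 0 higher of 38 measured in the authors' deposited table (Cxcl10, Tnfaip3, Ccl2 and the adhesion molecule Icam1, log2 ratio -1.28). Their median of -0.30 lay below all 10000 random lists. The 6 measured neutrophil markers had a median of -1.10 at the same time, below all 10000 random lists, with none of them called in the authors' deposited table. Immediate-early genes had 1 higher (Myc) and 3 lower (Nr4a1, Gadd45b and Zfp36, which encodes an mRNA-destabilising protein, -1.12) of 32 in the authors' deposited table, with a median of -0.20. The IGF axis and the gluconeogenesis and insulin list shared their 2 called members, Igfbp1 and the insulin receptor substrate Irs2 (-1.28), both lower in the authors' deposited table. The median of the second list was -0.08, at percentile 4.35 of the random lists. Acot3, an acyl-CoA thioesterase, was called higher (1.49), and Cyp2a4, a female-biased P450 (-1.66), the bile acid-induced repressor Nr0b2 (-1.39) and the macrophage receptor Marco (-1.79) were called lower in the authors' deposited table. Of the clock genes none of 20 was called in the authors' deposited table. Their median of -0.21 lay at percentile 0.09 of the random lists, and that of the interferon response genes, -0.18, at percentile 0.11 of the random lists. Other lists lay on the high side with few calls. Medians in the authors' deposited table were 0.31 for female-biased genes, above all 10000 random lists, and 0.21 for xenobiotic metabolism, at percentile 99.9 of the random lists. They were 0.17 for cholesterol synthesis, 0.14 for fatty acid synthesis and 0.14 for PPARA targets in the authors' deposited table, at percentiles 98.8, 96.5 and 97.8. With the length and GC trend removed, the female-biased median was 0.05, at percentile 89.2 of the random lists, and the other 4 lay at percentile 99.96 or higher. Without that step, the female-biased median lay at percentile 99.7 among random lists matched also on length and GC.

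Intronic reads gave 137 calls at 30 min in the authors' deposited table, 85 higher and 52 lower. They included genes whose gene body value had not passed: the introns of Onecut1 (log2 ratio 3.31, adjusted p = 1.5e-05), Igf1 (2.15, adjusted p = 0.00128) and the bile acid transporter gene Slc10a1 (2.88) were higher in the authors' deposited table. The introns of the gluconeogenic gene Pck1 were lower, with a log2 ratio of -3.17, as were those of the tyrosine aminotransferase gene Tat (-3.34), in the authors' deposited table, while their gene body values (-0.62 and -0.53) were not called. Intronic Igfbp1 stood at -5.79 and intronic Nr4a1 at -5.15 in the authors' deposited table. The gluconeogenesis and insulin list had 7 of 24 members lower over introns and 0 higher in the authors' deposited table, with a median of -0.63 below all 10000 random lists.

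**Figure D2:**
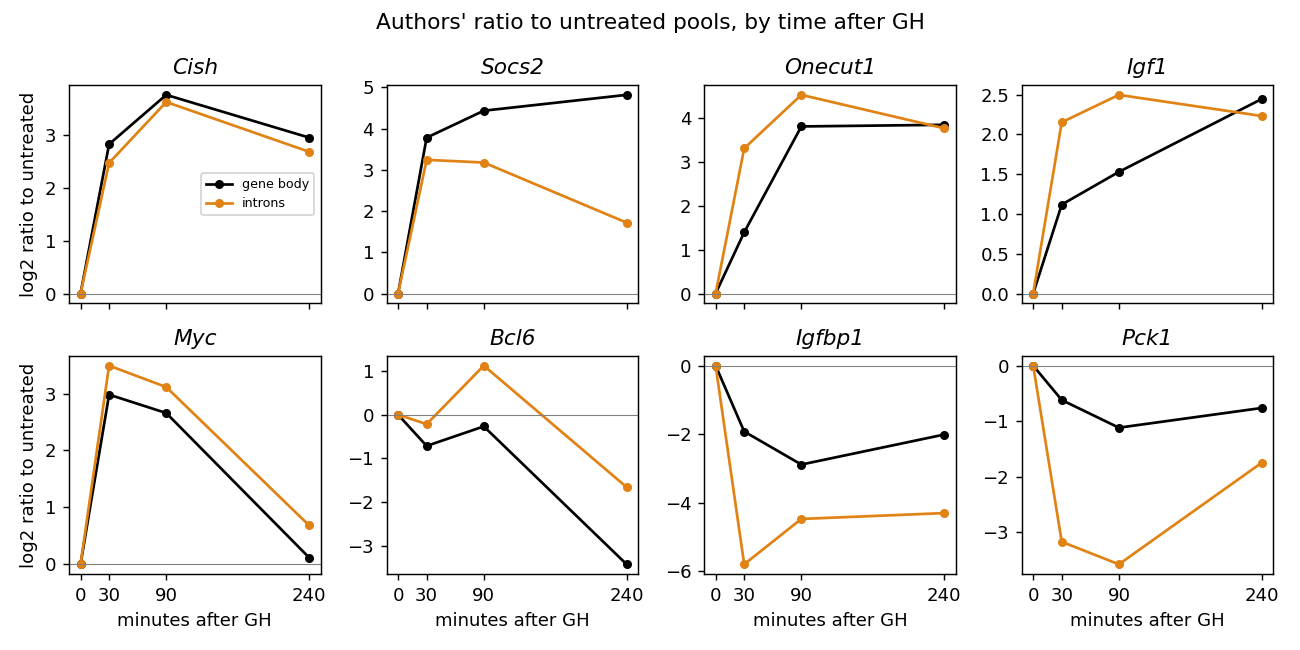
Log2 of the ratio to the untreated pools in the authors' deposited table (y axis) against min after GH (x axis) for 8 genes, over the gene body (black) and over introns (orange); untreated is 0 by definition and no error can be drawn, since the values are the authors' means. Intronic Igf1 was at 2.15 by 30 min, when its gene body value was 1.12, and Igfbp1 introns were at -5.79.

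The comparison of livers 90 min after GH with untreated livers called far more genes, with the feedback inhibitors and Igf1 higher. In the authors' deposited table, Socs2 was 21.6-fold higher (adjusted p = 2.1e-106), Cish 13.6-fold, Onecut1 14-fold (from 2.05 to 28.2 FPKM) and Igf1 2.89-fold (adjusted p = 3.3e-36). The log2 ratio of Igf1, 1.53, became 0.91 once a trend with transcript length and GC content was removed. Myc was still 6.31-fold higher in the authors' deposited table. Of the male-biased genes, 18 of 28 were lower in the authors' deposited table. There Mup10, a major urinary protein gene, was 22.7-fold lower. The fatty acid elongase gene Elovl3 was listed at 6.5 FPKM in untreated liver and at a level of few reads, 0.0639 FPKM, at 90 min. G6pc, which encodes the last enzyme of glucose release, was 4.17-fold lower and Igfbp1 7.38-fold lower in the authors' deposited table.

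The gene body calls numbered 3240 in the authors' deposited table, 1830 higher and 1410 lower, of which 521 differed by at least 2-fold. Ces2b was called higher from few reads, 0.0709 FPKM, to 8.18 FPKM in the authors' deposited table, so the size of its rise was not resolvable. After Socs2 (log2 ratio 4.44), the largest other increases in the authors' deposited table were Nrep (3.96), Onecut1 (3.81) and Cish (3.76). Next in the authors' deposited table were the glucuronosyltransferase gene Ugt2b38 (3.22), Tchh (3.15, from 0.143 FPKM), Zyg11a (3.10), Phlda1 (2.97) and Arid5a (2.94). The largest decreases in the authors' deposited table included Elovl3 (log2 ratio -6.51, to a level of few reads), A1bg (-4.53), Mup10 (-4.50), Mup1 (-3.61) and the sulfotransferase gene Sult5a1 (-3.51). Mup9, Mup17, Mup16 and Tff3, which encodes a trefoil peptide, were also called lower, from 11.7, 10.6, 4.55 and 1.59 FPKM to values under that of 3 reads in the authors' deposited table. The size of their falls was not resolvable. Mup5 is listed at 0 at 90 min, from 1.94 FPKM. Mup genes are near-identical in sequence, as are the Ugt2b genes, so values of single members are uncertain. Of the genes fixed beforehand, Igfals (0.88) rose and Fos (-1.98), Egr1 (-1.37) and Junb (-0.58) fell in the authors' deposited table, while Socs3 (0.08), Bcl6 (-0.27), Ghr (0.32, adjusted p = 0.0536) and Cux2 (-1.05) were not called.

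The early targets of GH and STAT5 had 10 higher and 2 lower of 26 measured members called in the authors' deposited table, with a median log2 ratio of 0.23 at percentile 99.5 of the random lists matched on expression. The gluconeogenesis and insulin list had 1 higher and 12 lower of 25 in the authors' deposited table, including Igfbp1 (-2.88), Ppp1r3g (-1.94), Tat (-1.09) and Pck1 (-1.12). Its median of -0.23 lay at percentile 9.78 of the random lists, and over introns the median of -0.68 lay at percentile 0.01 of the random lists, with 11 of 24 lower in the authors' deposited table. Male-biased genes had 1 higher and 18 lower of 28 in the authors' deposited table and a median of -0.57, below all 10000 random lists. Female-biased genes had 8 higher and 4 lower of 33, with the flavin monooxygenase gene Fmo2 (2.13) and the receptor gene Lifr (1.10, or 0.50 with the trend removed) higher and A1bg lower in the authors' deposited table. Cholesterol synthesis genes had 2 higher and 11 lower of 25 in the authors' deposited table (Fdps -0.94, Insig1 -0.81 and Mvk -0.89 lower, the sterol carrier gene Stard4 1.23 higher), and a median of -0.33. Heat shock genes had 7 of 18 higher and 0 lower in the authors' deposited table, among them Chordc1 (1.13, or 0.54 with the trend removed), Hsp90aa1 (1.03) and Hsph1 (1.15).

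Immediate-early genes had 5 higher and 13 lower of 32 in the authors' deposited table (Nr4a1 -3.06, Gadd45g 1.60), with a median of -0.34. Clock genes had 5 higher and 8 lower of 20 in the authors' deposited table, with the clock output gene Dbp (-1.08), Cry2 (-0.99) and Per1 (-1.13) lower. Secreted plasma proteins had 2 higher and 13 lower of 26 in the authors' deposited table, with Apob (0.90) higher and Apoa1 (-0.60), Apoc3 (-0.60) and Ttr (-0.56) lower. With the trend removed these 4 values became 0.055, -0.17, -0.18 and -0.41. The plasma protein median of -0.30 lay at percentile 9.41 of the random lists. Ribosome biogenesis genes had 12 higher and 1 lower of 33 in the authors' deposited table (Nop58 1.36, or 0.67 with the trend removed, Gnl3 0.90 and Tsr1 0.97 higher). Over introns there were 1507 calls in the authors' deposited table, 804 higher and 703 lower, and 499 genes were higher and 319 lower on both measures, which come from the same pools.

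The direction of the calls at 90 min moved with transcript length. In the authors' deposited table, 4.82% of the 456 called genes with a longest transcript under 1500 nt were higher, against 96.8% of the 711 with 6000 nt or more. Across genes, which are not independent replicates, the log2 ratio correlated with transcript length at Spearman rho = 0.486 and with GC content at -0.507 in the authors' deposited table, and with length at 0.0813 at 30 min and 0.185 at 240 min. The correlation with GC content was -0.579 at 30 min and -0.378 at 240 min in the authors' deposited table. With this trend removed, a step chosen after seeing the data, 2721 of 2951 called genes kept their direction at 90 min. The median of the immediate-early list then moved from -0.34 to -0.06, at percentile 15.1 of the random lists, while among random lists matched also on length and GC its median without that step lay at percentile 0.15. The median of the plasma proteins moved to -0.05. The male-biased list stayed at -0.49, below all 10000 random lists.

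**Figure D3:**
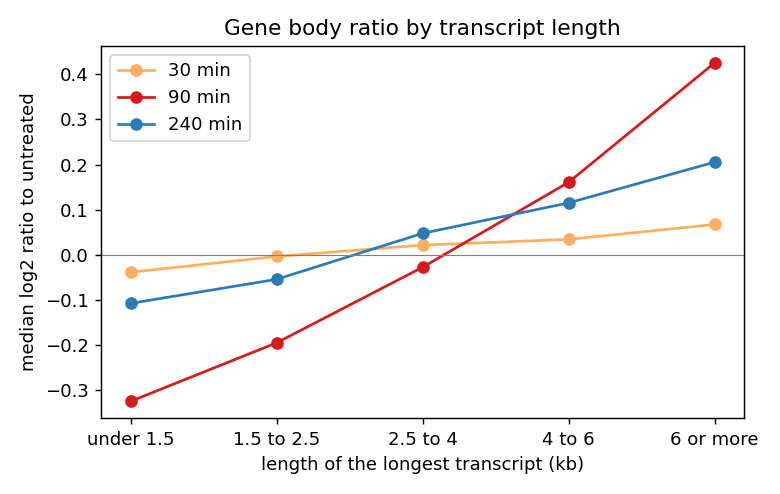
Median log2 ratio to untreated in the authors' deposited table (y axis) for genes grouped by the length of their longest transcript (x axis, kb), over the gene body, at 30, 90 and 240 min after GH. At 90 min the median went from -0.325 in the shortest class to 0.425 in the longest.

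At 240 min 25 of 33 genes for making ribosomes, 17 of 24 of the unfolded protein and stress response and 8 of 25 for making cholesterol were higher in the authors' deposited table. Among inflammatory genes 15 of 38 and among immediate-early genes 17 of 32 were lower in the authors' deposited table. In the authors' deposited table, Igf1 was 5.45-fold higher (from 12.8 to 72.2 FPKM, adjusted p = 6.1e-56), Igfals 3.6-fold and Socs2 28.3-fold, while Cish stood at 7.74-fold and Myc, at 1.09-fold (adjusted p = 1), was not called. The transcriptional repressor Bcl6 was 10.7-fold lower (adjusted p = 3.2e-35) and Socs3, an inhibitor induced by inflammatory cytokines, 4.99-fold lower in the authors' deposited table. The snoRNP component Nop58 was 4.32-fold higher and Dnajb9, a chaperone of the endoplasmic reticulum, 4.07-fold higher in the authors' deposited table.

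Gene body calls numbered 2642 in the authors' deposited table, 1621 higher and 1021 lower, of which 781 differed by at least 2-fold. Ces2b and Bhlha15 were called higher from few reads, 0.0709 and 0.0849 FPKM, to 17.5 and 1.51 FPKM in the authors' deposited table, and the size of these rises was not resolvable. The largest other increases in the authors' deposited table were Ugt2b38 (log2 ratio 5.05, from 0.242 FPKM), Nrep (4.97), Socs2 (4.82) and the potassium channel gene Kcnt2 (4.36). Next were Onecut1 (3.85), the acetoacetyl-CoA synthetase gene Aacs (3.23) and Cish (2.95) in the authors' deposited table. Prok1 was called higher and is listed at 0 in untreated liver and at 2.13 FPKM at 240 min in the authors' deposited table. Decreases in the authors' deposited table were led by A1bg (-4.82), Mup9 (-4.71), Elovl3 (-4.62), Mup1 (-3.57), Mup17 (-3.53), Bcl6 (-3.42), Mup16 (-3.32) and Fam13a (-3.11), and Mup5, at 0.121 FPKM and under the level of 3 reads, and Tff3, listed at 0, were also called lower. The values of A1bg, Mup9, Elovl3, Mup1 and Mup16 at 240 min rest on few reads (0.204, 0.321, 0.24, 0.499 and 0.376 FPKM in the authors' deposited table), so their order is uncertain. Ghr, the GH receptor gene, was called higher (0.64), Fos (-2.47), Egr1 (-2.39) and Junb (-2.39) lower, and Cux2 (-1.29) was not called in the authors' deposited table.

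Ribosome biogenesis genes had 25 of 33 members higher and 0 lower in the authors' deposited table, with Tsr1 (1.82), Nolc1 (1.76) and the RNA helicase gene Ddx21 (1.31) beside Nop58 (2.11), and a median log2 ratio of 0.75, above all 10000 random lists matched on expression. The unfolded protein and integrated stress list had 17 of 24 higher and 0 lower in the authors' deposited table (Dnajb9 2.02, Creld2 1.71, Manf at 2.82-fold and Hspa5, the chaperone BiP, 1.22), and a median of 0.70, above all 10000 random lists. Heat shock genes had 9 of 18 higher (Hsp90aa1 1.27, Hsph1 1.22, Hspa8 0.90) and 0 lower in the authors' deposited table. Over introns 2 of 16 heat shock genes were higher and 0 lower, with a median of -0.03 at percentile 55.3 of the random lists. Cholesterol synthesis genes had 8 of 25 higher and 0 lower in the authors' deposited table, among them Sqle (1.16) and Idi1 (1.22), with a median of 0.24 at percentile 98.9 of the random lists. With the length and GC trend removed, the gene body medians of these 4 lists were 0.70, 0.70, 0.49 and 0.21.

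Immediate-early genes had 1 higher and 17 lower of 32 in the authors' deposited table, including Junb, Nr4a1 (-2.59), Zfp36 (-1.96) and Egr1, and a median of -0.50, below all 10000 random lists. Gluconeogenesis and insulin genes had 2 higher and 11 lower of 25 in the authors' deposited table (Igfbp1 -2.01, Sds -1.23, Ppp1r3g -1.84 and Tat -1.04 lower), and male-biased genes 4 higher and 14 lower of 28, with Ugt2b38 higher and Mup10 (-2.97) lower. In the authors' deposited table the acute-phase and inflammatory list had 5 higher and 15 lower of 38 over the gene body (Cxcl1 -2.31, Tnfaip3 -1.79 and Nfkbia -1.08 lower), while Kupffer cell genes had 5 of 15 lower at that time and the neutrophil markers a median of -0.70, at percentile 0.09 of the random lists. At 90 min the acute-phase and inflammatory list had 4 higher and 14 lower of 38 in the authors' deposited table, with a median of -0.16 at percentile 46 of the random lists, and the neutrophil markers a median of 0.63. Over introns 31 of the 38 measured acute-phase and inflammatory genes were lower and 1 higher at 240 min in the authors' deposited table, with a median of -1.71 below all 10000 random lists. Introns of the serum amyloid genes Saa1 (-4.64) and Saa2 (-4.95), whose sequences are near-identical so that single values are uncertain, and of the metallothionein genes Mt1 (-5.55) and Mt2 (-5.11) fell, as did those of Socs3 (-4.84), while the gene body values of Saa1 (-0.41) and Mt2 (-0.70) were not called in the authors' deposited table. The haem synthesis gene Alas1 (2.02) rose and the nuclear receptor gene Nr1i3 (-1.30) and Cyp3a25 (-0.87), a member of a family with near-identical copies, fell among xenobiotic metabolism genes (1 higher and 8 lower of 33 in the authors' deposited table).

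Intronic calls at 240 min numbered 1198 in the authors' deposited table, 555 higher and 643 lower. The authors' intronic ratios differ from the quotient of the FPKM means by a median log2 of -0.144 at 30 min, -0.568 at 90 min and -0.387 at 240 min in the authors' deposited table, so intronic changes are given relative to that scaling. Quotients of the FPKM means with pseudocounts of 1 and 0.1 gave smaller falls. The intronic gluconeogenesis median was then -0.12 and -0.40 at 30 min, and -0.09 and -0.12 at 90 min. The intronic acute-phase median at 240 min was -0.70 and -1.12. These medians all lay at percentile 0.01 or lower of the random lists.

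**Figure D4:**
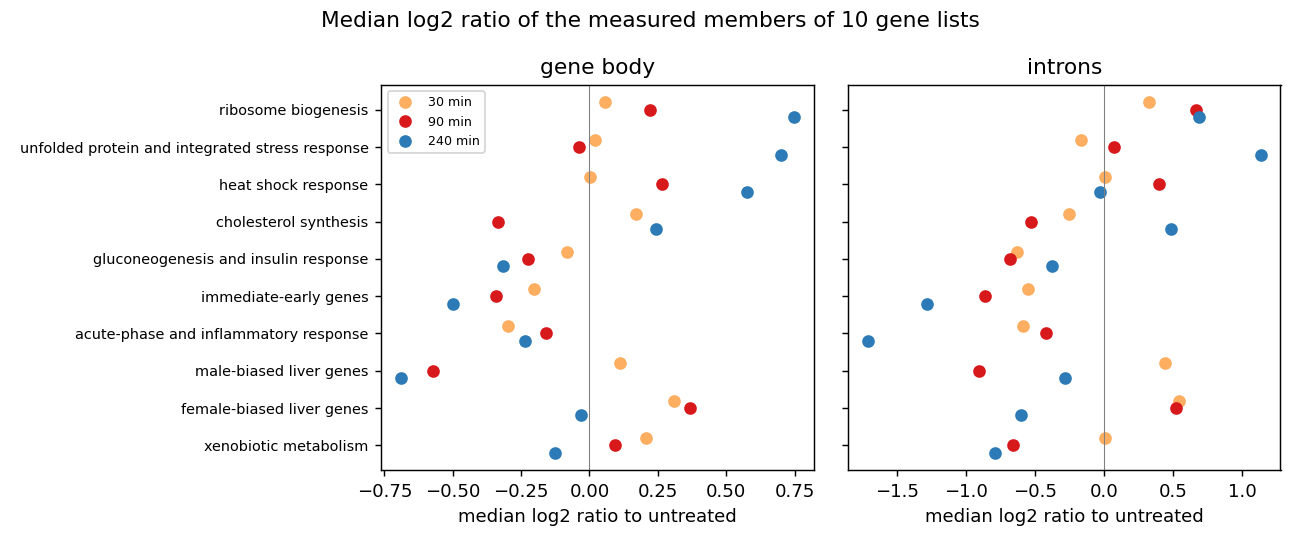
Median log2 ratio to untreated in the authors' deposited table (x axis) of the measured members of 10 gene lists (y axis), over the gene body (left) and over introns (right), at 30, 90 and 240 min after GH. Ribosome biogenesis reached 0.75 and the unfolded protein list 0.70 over the gene body at 240 min, and acute-phase introns -1.71.

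Across times, 820 genes were called higher and 388 lower at both 90 and 240 min in the authors' deposited table, and 16 were higher and 13 lower at all 3 times. Independent lists would share 169 higher and 82.1 lower genes at 90 and 240 min. Simulated noise of equal spread with a shared control, cut to lists of the same size, gave 553 and 331. At 30 and 90 min 23 higher and 20 lower genes were shared in the authors' deposited table, with 18.6 and 20.7 in the simulation. At 30 and 240 min the shared genes were 16 and 23 in the authors' deposited table, with 17.5 and 18.2 in the simulation. Over introns, 59 higher and 41 lower genes were shared at 30 and 90 min in the authors' deposited table, with 34.9 and 21.3 in the simulation. At 90 and 240 min the intronic numbers were 208 and 330 in the authors' deposited table, with 149 and 154 simulated. At 30 and 240 min they were 27 and 38 in the authors' deposited table, with 28.2 and 19.8 simulated. The 2 untreated pools cannot be split, so part of the sharing may come from them. Log2 ratios correlated across genes at Pearson r = 0.621 between 90 and 240 min and 0.494 between 30 and 90 min in the authors' deposited table. The noise gave 0.498 and 0.501, which its equal spread fixes by construction. Between 30 and 240 min r was 0.414 in the authors' deposited table, against 0.504 for the noise, so its equal spread may not hold in these data. Over introns r was 0.630, 0.617 and 0.491 for 30 and 90, 90 and 240, and 30 and 240 min in the authors' deposited table, against 0.493, 0.491 and 0.496. Differences between times were not tested, since the table compares each time with untreated liver only.

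Some markers of other liver cells were also called. Kupffer cell and macrophage genes had 1, 4 and 5 of 15 lower and none higher at 30, 90 and 240 min in the authors' deposited table, among them the complement gene C1qa (-0.56 at 90 min) and the macrophage growth factor receptor gene Csf1r (-0.65 at 240 min), with medians of -0.12, -0.35 and -0.44. With the length and GC trend removed these medians were -0.07, -0.13 and -0.32, at percentiles 7.36, 5.98 and 0.26 of the random lists. Neutrophil genes had medians of -1.10, 0.63 and -0.70 over 6 measured members in the authors' deposited table, and S100a9 stood at -1.44, which was not called, 0.61 and -0.72. Cholangiocyte genes had 3 higher and 1 lower of 6 at 240 min in the authors' deposited table, with Tspan8 (2.61), Spp1 (1.11) and Krt19 (1.80) higher and Krt23 (-2.18) lower. Periportal hepatocyte genes had 2 higher and 6 lower of 16 at 90 min and 2 higher and 8 lower of 16 at 240 min, and pericentral genes 3 higher and 3 lower of 14 and 1 higher and 2 lower of 14 in the authors' deposited table. Random lists matched on expression had means of 1.31 higher and 5.30 lower for the periportal list at 90 min, and 1.71 and 2.25 at 240 min. For the pericentral list these were 1.74 and 3.12, then 1.90 and 1.58. Medians at 30, 90 and 240 min were -0.17, -0.11 and -0.18 for sinusoidal endothelium, 0.09, 0.09 and -0.17 for stellate cells and fibroblasts, -0.33, -0.65 and -0.37 for lymphocytes and 0.28, -0.37 and -0.10 for erythroid cells in the authors' deposited table. The pancreatic and adipose lists had too few measured members and the mitochondrially encoded list had none.

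The remaining lists, at 90 and 240 min in the authors' deposited table, were as follows. Interferon response genes had 6 higher and 5 lower of 29 and 5 higher and 3 lower of 29. Random lists matched on expression had means of 4.56 and 3.69, then 4.30 and 2.42. Fatty acid and triglyceride synthesis genes had 2 higher and 7 lower of 24 and 4 higher and 5 lower of 24, with the desaturase gene Scd1 (-0.90) lower and the carboxylase gene Acacb (1.20) higher at 240 min. The random means for this list were 3.04 and 5.25, then 3.34 and 2.58. Fatty acid oxidation and PPARA target genes had 2 higher and 7 lower of 30 and 2 higher and 4 lower of 30. These compare with random means of 3.30 and 7.57, then 3.68 and 3.57. Bile acid genes had 3 higher and 6 lower of 24 and 1 higher and 5 lower of 24, with the sterol transporter genes Abcg8 (-1.95) and Abcg5 (-1.36) lower and Slc10a1 (1.06) higher at 240 min. For the bile acid list the random means were 2.92 and 5.52, then 3.42 and 2.59. Glucocorticoid targets had 2 higher and 7 lower of 22 and 2 higher and 5 lower of 22, with Fkbp5 (1.95) higher at 240 min. Here the random means were 3.03 and 4.35, then 2.97 and 2.38. At the later time the early targets of GH and STAT5 had 10 higher and 7 lower of 26, female-biased genes 10 higher and 7 lower of 33, clock genes 2 higher and 5 lower of 20 and plasma proteins 2 higher and 7 lower of 26 measured members called in the authors' deposited table. The IGF axis had 4 higher and 3 lower of 12 and 3 higher and 3 lower of 12, with medians of 0.19 and -0.38 in the authors' deposited table, the second at percentile 0.19 of the random lists. At 240 min the medians of the bile acid list (-0.24) and of the glucocorticoid targets (-0.33) in the authors' deposited table lay at percentiles 1.06 and 0.13. Cell cycle genes had 1 higher and 0 lower of 11 and 1 higher and 0 lower of 11, and replication-dependent histone genes 0 higher and 2 lower of 5 and 0 higher and 0 lower of 5. The unfolded protein list had 3 higher and 5 lower of 24 at 90 min, against random means of 3.05 and 5.38. Xenobiotic metabolism genes had 8 higher and 1 lower of 33 over the gene body at 90 min, but 1 higher and 13 lower of 31 over introns in the authors' deposited table. The medians were 0.09 and -0.66. From quotients of the FPKM means with pseudocounts of 1 and 0.1, the intronic median was -0.04 and -0.08, at percentiles 0.005 and 0 of the random lists. The size of the intronic fall thus depends on the scaling. At 240 min 1 higher and 17 lower of 31 were called over introns.

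Positions in the mm9 build, as the table gives the gene body with starts counted from 1, are chromosome 10, 94874124 to 94879491 for Socs2, chromosome 9, 107199020 to 107204292 for Cish, chromosome 9, 74709728 to 74737454 for Onecut1, chromosome 10, 87323856 to 87378515 for Igf1, chromosome 16, 23965138 to 23988698 for Bcl6 and chromosome 11, 7097790 to 7102549 for Igfbp1. Those of Myc (chromosome 15, 61816896 to 61821916), Ces2b (chromosome 8, 107355544 to 107362552), Nop58 (chromosome 1, 59741850 to 59768354) and Dnajb9 (chromosome 12, 45306884 to 45311055) are on the same build.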

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

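The tests on overlaps, calls at any time under other thresholds, the filter on calls and the removal of the length and GC trend were chosen after seeing the data. With an adjusted p below 0.01, 40 genes were called at 30 min over the gene body, and 71 at 30 min and 777 at 240 min over introns. With at least 2-fold, 521 were called at 90 min, 781 at 240 min and 1143 at any time, against 4639 without that limit. Fewer genes pass a stricter limit by construction. The overlaps at an adjusted p below 0.01 were 12 genes higher at 30 and 90 min, 510 higher and 201 lower at 90 and 240 min, and 8 higher and 15 lower at 30 and 240 min. With at least 2-fold they were 122 higher and 55 lower at 90 and 240 min. With the trend removed, Abcc2 (-0.018), Ptprb (-0.20), Reln (-0.063) and Slc1a2 (-0.11) changed sign at 90 min. The step moves genes with long transcripts down at 90 min by construction. Of the named gene values, 337 moved by less than 1.5 times under this step and 49 moved by more with a pseudocount of 1. No paired analysis was possible because the columns carry no value per pool. For the same reason leaving out each pool, the pool number as a factor, filters on counts, other normalizations, tools and settings of the spread, set tests and tests between times were not run. The number of lists outside the central 95% moved by less than 1.5 times under every alternative run, but which lists these were changed. With the trend removed at 90 min over the gene body, the immediate-early, bile acid, Kupffer cell and histone lists came inside (percentiles 15.1, 88.1, 5.98 and 6.16). The fatty acid synthesis, gluconeogenesis, clock, glucocorticoid and endothelium lists moved outside (percentiles 1.48, 0, 0.13, 2.44 and 2.0). Depth limits the values of genes with few reads, and with no value per pool a single pool that decides a value cannot be seen.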

Other observations

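The genes of this and the next paragraphs up to the weighing of transcript length, and the tests on the number of calls at 30 min and on male-biased genes, were chosen after their values were seen. Some interferon-inducible GTPase genes were called higher at 90 min in the authors' deposited table: Irgm2 (log2 ratio 1.53), Ifi47 (1.29), Irgm1 (0.98), Igtp (0.92) and Iigp1 (0.80). Their introns stood at 2.23, 3.21, 1.99, 2.01 and 2.22 at 90 min in the authors' deposited table, and at 240 min, when Ifi47 was at 2.28 over the gene body, at -1.15, 0.28, -0.26, -0.96 and -0.54, none of them called. Gbp3, another such gene, was not called at 90 min (ratio 0.911 in the authors' deposited table). The fixed interferon response list had a gene body median of 0.02 at 90 min, at percentile 62.9 of the random lists. The chemokine gene Cxcl10 was lower at every time in the authors' deposited table, with -2.35, -1.64 and -1.24.

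Gene body and introns went opposite ways for 6 genes that were higher over the gene body and lower over introns at 240 min in the authors' deposited table. The fibrinogen genes Fga (0.74 and -1.14), Fgb (0.65 and -1.47) and Fgg (0.74 and -0.88), the metalloreductase gene Steap4 (0.88 and -2.72) and Lrg1 (0.92 and -0.74) were among them in the authors' deposited table. Ttr, which encodes transthyretin, was the reverse at -0.61 over the gene body and 0.76 over introns in the authors' deposited table.

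Genes called in opposite directions at 90 and 240 min numbered, in the authors' deposited table, 26 higher then lower and 19 lower then higher. Independent lists would give 106.5 and 130.3. Both comparisons share the same untreated pools, which by itself lowers such counts, so nothing is concluded from this difference. Cxcl1 (0.50 and -2.31), Foxq1 (0.86 and -1.50) and the activin antagonist gene Fst (0.68 and -1.46) were higher then lower in the authors' deposited table. G6pc (-2.06 and 0.53), Sqle (-0.98 and 1.16), Mfsd2a (-2.40 and 1.06) and Errfi1 (-0.37 and 1.31) were lower then higher in the authors' deposited table. The difference between the times was not tested.

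At 90 min called genes with long transcripts were mostly higher and those with short transcripts mostly lower. The trend was also present among the 7363 genes that were not called, with a rho of 0.326 between log2 ratio and transcript length, so a difference in RNA fragmentation or library preparation between the pools is a candidate explanation. A response to GH that depends on length cannot be separated from it, since each group has its own pools, and was not tested. After the trend was removed, medians lay above all random lists for ribosome biogenesis, the unfolded protein list and heat shock at 240 min (percentile 100 for each) and at percentile 99.6 for cholesterol synthesis, and below all random lists (percentile 0) for male-biased genes at 90 min and immediate-early genes at 240 min, which argues against the trend as the whole cause of these. The gluconeogenesis and plasma protein lists at 90 min had not stood apart from matched lists before the step (percentiles 9.78 and 9.41) and were at percentiles 0 and 46.5 after it, so they are no test of the trend (gluconeogenesis was at 5.95 among lists matched also on length and GC).

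Only 64 genes were called at 30 min. The pools at 30 min held 0.963 times the reads of those at 240 min, which argues against lower depth. Of genes with a mean of 5 to 100 FPKM that differed 2 to 3-fold, 37.7% were called at 30 min against 93.5% at 90 min and 95.6% at 240 min. An adjusted p can be stricter where fewer genes change, and how it was adjusted is not given. These shares therefore cannot decide on smaller or fewer changes. A larger spread between the 30 min pools stays open as a hypothesis and could not be tested without values per pool.

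Male-biased Mup1, Mup10, Mup16, Elovl3 and Hsd3b5, of which the Mup genes share near-identical sequence and are uncertain, were at or below 0.25 of the untreated level at 90 min in the authors' deposited table, while at 30 min, with none called, the ratios to untreated were 5.11, 5.81, 0.39, 0.514 and 5.35, and Mup16 at 90 min was under the level of 3 reads. Their intronic ratios at 30 min, none called, were 1.28 for Mup1, 8.21 for Mup10, 1 for Mup16, 0.171 for Elovl3 and 10.2 for Hsd3b5. The intronic ratio of Mup16 was also 1 at 90 and 240 min, and 0.171 was also listed for introns of Fos and Ccl5 at 30 min. Introns of Mup21 were called lower at 30 min (ratio 0.0823), and Mup21 is among the 10 genes used below for comparison. The uncalled values of Mup1, Mup10, Mup16, Elovl3 and Hsd3b5 cannot tell whether their synthesis had stopped by then. If GH had stopped their synthesis at once, decay would need a median half-life of 19.98 min over 90 min, or 10.5 min from the uncalled 30 min value. For 10 genes whose introns had dropped to 0.2 of the untreated level or less by 30 min, half-lives were counted from the injection. The shortest was 11.9 min and the median 19.1 min. A later stop of their synthesis would make these half-lives shorter. With the starting value also unsettled, decay stays open. Animals in the untreated or 30 min pools that kept more of these transcripts (mixed pools) may be another cause, but 0 of 5 male-biased genes with a mean of at least 5 FPKM over the untreated and 30 min groups and a change over 2-fold at 30 min were called, against 40 of 89 other genes of that level and size of change, too few to tell. Both tests replaced first versions whose outcome had been seen: from the 30 min value alone the falls were too fast for decay, and a count of uncalled 2-fold changes had favoured mixed pools but only restated the pattern.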
